A study of Homo sapiens with 13 samples.

How the data were processed

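The series holds 13 poly-A RNA sequencing libraries of K562 cells, harvested after 48 h in RPMI medium with 10% fetal bovine serum, with or without exosomes. Per the labels, RNA was taken with TRIzol and libraries were made with a NEBNext Ultra kit. That kit as described does not mark the strand, so reads of overlapping genes on opposite strands cannot be told apart. The groups were NC (n = 3), H-Exo (n = 3), S-Exo (n = 3) and R-Exo (n = 4), taken from the sample labels.

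The authors deposited 1 table that holds, per the file headers, counts and FPKM for each gene and library. The counts were whole numbers in each library, and the deposited FPKM values were not log-transformed. Per the submitters' processing notes TopHat2, Picard, SAMtools 0.1.18 and GATK were used, with no role given for each. The counting tool, genome build, annotation release and FPKM tool are not given in the sources used here. The table also holds the authors' DESeq2 calls for 4 pairs of groups, at an unadjusted p of 0.05 and a fold of 1.5. The table has 19974 genes with a symbol and 6983 unannotated loci. 19 continuation lines without counts were skipped, and 12 names that a spreadsheet had turned into dates were restored. Chromosome positions came from GENCODE 29 on GRCh38 by Ensembl identifier, whatever build the authors used.

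Library totals were 31683608, 32110321 and 29757999 counts for NC, 35103565, 32660741 and 33148002 for H-Exo, 33646097, 32411211 and 31339739 for S-Exo, and 32723735, 32615895, 33464537 and 38215543 for R-Exo. A gene with 0 counts was given a floor of 3 counts per library (0.106 CPM).

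Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 16941, of which 13332 have a symbol. TMM factors were computed, and all 13 libraries entered 1 quasi-likelihood fit with robust dispersion (9 residual degrees of freedom, common biological coefficient of variation 0.289). The 6 pairs of groups were tested as contrasts, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The SE of a log2 fold change was its size divided by the square root of the F statistic. DESeq2 1.42.0 on the same genes and limma 3.58.1 on log2 FPKM were run beside it.

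Before the data were examined 36 gene lists were fixed, covering blood lineages, lipid metabolism, stress responses, immunity, signalling, cell cycle, translation, mitochondria and markers of other cell types. They were tested with camera on log2 CPM (prior count 2, preset correlation 0.01), and 35 had at least 5 tested genes. KEGG pathways with 10 to 500 tested genes, as annotated in the deposited table, were tested with a one-sided Fisher's exact test in each direction. Principal components were computed on 11345 genes.

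Genes named in the text followed a rule fixed before the data were examined. For each pair it took the 8 largest rises and 8 largest falls past the threshold among genes with a symbol, at least 5 CPM in the higher group and no overlap between libraries. Where no gene passed, the 4 of lowest p were named. For each list with a member past the threshold, or whose test passed, up to 4 members of lowest p could be named. Some items that the rule gave are withheld for evaluation and left out of the text.

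The method was tested on simulated data made from these libraries. At 3 libraries against 3, edgeR recovered 27.6% of genes changed 2-fold and 70.1% of those changed 4-fold, with 3 false calls among 16237 genes. At 4 against 3 the shares were 29.9% and 69.5%, with 5 false calls among 16223. DESeq2 made 59 and 38 false calls in the same data. The planted gene list was the only list past in both. The simulated genes varied independently, so this does not test lists whose genes vary together. In the real data the estimated correlation was 0.80 for ribosomal protein genes. The planted pathway ranked first in both, but 77 pathways passed in each.

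Alternatives covered the scaling, the filter, the tool, FPKM in place of counts, the 2 groups alone, a replicate block, a 2-fold minimum, other list tests and leaving out each library. Their effect is given in the closing section. Levels of sex-specific genes are not reported, and no library was left out of the main analysis.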

Results

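RNA sequencing was carried out on K562 cells, an established chronic myeloid leukaemia (CML) cell line, cultured for 48 h with or without exosomes, the small vesicles that cells release. The 13 libraries form 4 groups: untreated cells (NC, n = 3), cells given H-Exo (n = 3), cells given S-Exo (n = 3) and cells given R-Exo (n = 4). The series title describes plasma exosomes from CML patients, and the labels do not spell out the letters H, S and R. They also do not say whether the replicates were separate cultures or exosomes of separate donors, so each p-value measures only the spread between these samples, which may be technical. The deposited table held counts for 19974 genes with a symbol and 6983 unannotated loci, with 29757999 to 38215543 counts per library. Where all libraries of a group had 0 counts, the fold is a lower bound against a floor of 3 counts per library, or 0.106 CPM (counts scaled to the library total). Such bounds and the intervals given cover counting error only. Levels below are the mean ± SD in TMM-normalised CPM, the first group of the pair given first, with n = 3 for NC, H-Exo and S-Exo and n = 4 for R-Exo. Fold changes are log2 values ± SE. Positions are those of GENCODE 29 on GRCh38.

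The R-Exo libraries separated from the other 9 along the first principal component, which held 46.1% of the variance. The second component, with 37.8%, set H-Exo 3 (score -80.7) and R-Exo 4 (score -42.8) apart from their groups. In these 2 libraries loci without a gene symbol took 2.38% and 2.58% of the counts, against 3.65% to 4.13% in the other 11. Mitochondrially encoded genes held 7.76% to 11.3% of the counts per library.

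**Figure D1:**
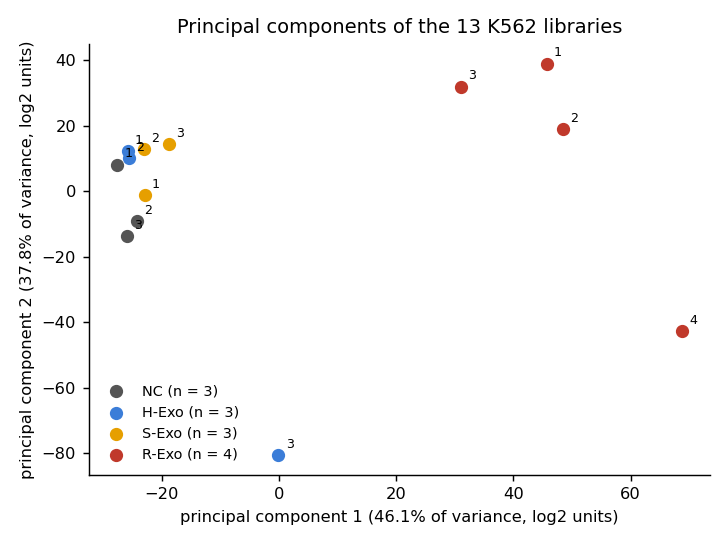
Scores of the 13 libraries on the first (x axis, 46.1% of variance) and second (y axis, 37.8% of variance) principal components of log2 CPM over 11345 genes; each point is a library, coloured by group and numbered by replicate. The 4 R-Exo libraries lie right of the other 9, and H-Exo 3 and R-Exo 4 lie lowest.

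The comparison of H-Exo with NC asks whether exosomes of the H kind alter the transcriptome of the leukaemia cells. No single gene passed. Among the lowest unadjusted p-values were those of SKIL, a repressor of TGF-beta signalling (3.99 ± 1.29 against 15 ± 0.955 CPM), AC092647.5 (0.729 ± 0.281 against 0 CPM) and FAM124B (4 ± 1.3 against 2.24 ± 0.187 CPM). For all of these the edgeR adjusted p was 1. Genes of 3 lists were higher together in H-Exo. The erythroid list had a median log2 change of 0.21 over 42 tested genes (camera adjusted p = 9.34e-04, and adjusted p = 0.719 with an estimated correlation), with 0 members past when adjusted over the list alone. Its members of lowest p were TRIM58, a ubiquitin ligase of late erythroblasts (9.36 ± 0.636 against 5.8 ± 1.86 CPM), and LMO2, a blood transcription cofactor (18.3 ± 3.06 against 13.5 ± 2.15 CPM). The immediate early and MAPK feedback list had a median of 0.19 over 30 genes (camera adjusted p = 3.43e-04, and adjusted p = 0.63 with an estimated correlation), with 0 past when adjusted over the list alone. In it, the growth-factor response gene EGR1 stood at 181 ± 56.9 against 107 ± 11.9 CPM and SPRY2, a feedback inhibitor of receptor kinases, at 16.5 ± 3.16 against 12.5 ± 0.888 CPM. The G1/S and DNA replication list had a median of 0.15 over 30 genes (camera adjusted p = 0.00118, and adjusted p = 0.656 with an estimated correlation), with 0 past when adjusted over the list alone. Among its members UNG, a base excision repair enzyme, stood at 27.6 ± 14.3 against 16.4 ± 1.76 CPM and RRM2, a subunit of ribonucleotide reductase, at 209.6 ± 62.5 against 163 ± 5.67 CPM.

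In edgeR's quasi-likelihood test 0 of 16941 genes passed, with 426 at an unadjusted p under 0.05 against 847 by chance. DESeq2 called 7 and limma on FPKM 0. Each of the 3 lists lost its call without H-Exo 3, where 3 other lists were lower and 0 higher (for the first 3, camera adjusted p = 0.513, 0.0728 and 0.402 in the order given), and the erythroid list then pointed down.

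S-Exo was compared with NC by the same test. No single gene passed here either, but genes of 10 lists moved together. Immediate early and MAPK feedback genes were higher (median 0.36 over 30 genes, camera adjusted p = 1.07e-06, and adjusted p = 0.455 with an estimated correlation), with 9 members past when adjusted over the list alone and 0 over all genes tested. FOS, part of the AP-1 transcription factor, stood at 29.7 ± 0.583 against 9.04 ± 2.72 CPM and EGR1 at 311 ± 19.8 against 107 ± 11.9 CPM. The nuclear receptor NR4A2 stood at 9.87 ± 0.242 against 6.09 ± 0.541 CPM and the MAPK phosphatase DUSP1 at 18.7 ± 2.12 against 9.24 ± 0.949 CPM. The edgeR adjusted p was 0.4 for both EGR1 and FOS. Erythroid genes were higher as a list (median 0.35 over 42, camera adjusted p = 1.26e-04, and adjusted p = 0.569 with an estimated correlation), led by TRIM58 (10.6 ± 2 against 5.8 ± 1.86 CPM) and the mitochondrial iron importer SLC25A37 (224 ± 0.991 against 169.9 ± 4.17 CPM), with 0 past when adjusted over the list alone. The megakaryocyte and platelet list (median 0.21 over 21, or 0 with genes at 0 counts set to their bound, camera adjusted p = 0.045, and adjusted p = 0.465 with an estimated correlation) had 2 members past when adjusted over the list alone. They were TUBB1, the tubulin of platelets (5.38 ± 0.414 against 1.54 ± 0.228 CPM), and CAVIN2, a caveola protein (75.4 ± 10.7 against 44.9 ± 4.26 CPM).

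The remaining 7 lists had 0 members past when adjusted over the list alone. Ribosomal protein genes were lower (median -0.38 over 46, camera adjusted p = 4.49e-13, and adjusted p = 0.569 with an estimated correlation), with RPS24 at 1074 ± 15.5 against 1484 ± 154 CPM. Lower too were mitochondrially encoded genes (median -0.19 over 13, camera adjusted p = 0.045, and adjusted p = 0.833 with an estimated correlation) and the amino acid response genes that ATF4 controls (median -0.12 over 29, camera adjusted p = 0.0478, and adjusted p = 0.833 with an estimated correlation). The stress factor gene DDIT3 in the latter stood at 151 ± 9.87 against 219 ± 20.3 CPM. Higher lists included G1/S and DNA replication (median 0.18 over 30, camera adjusted p = 0.014, and adjusted p = 0.569 with an estimated correlation), with the helicase subunit MCM4 at 427 ± 12.2 against 318 ± 16.4 CPM. G2/M and mitosis genes were higher (median 0.16 over 29, camera adjusted p = 0.045, and adjusted p = 0.465 with an estimated correlation), with the spindle checkpoint kinase BUB1 at 205 ± 25.1 against 143 ± 22 CPM. Heat shock genes were higher (median 0.21 over 18, camera adjusted p = 0.0205, and adjusted p = 0.465 with an estimated correlation), with the chaperone HSPH1 at 99.1 ± 10 against 66.5 ± 7.35 CPM. Cholesterol synthesis and uptake genes were higher (median 0.16 over 28, camera adjusted p = 0.0186, and adjusted p = 0.833 with an estimated correlation), with HMGCS1, an early enzyme of the pathway, at 172 ± 47.8 against 94.8 ± 28.9 CPM.

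For single genes edgeR's test gave 0 of 16941, with 1244 at an unadjusted p under 0.05 against 847 by chance. DESeq2 called 120, limma on FPKM 0, edgeR on these 2 groups alone 203, and edgeR without H-Exo 3 and R-Exo 4 called 565. The genes of lowest p included CYFIP2, an actin regulator (4.24 ± 0.797 against 9.53 ± 0.228 CPM), and CDKN2AIP (30.8 ± 2.3 against 15.1 ± 3.38 CPM), both at an edgeR adjusted p of 0.4. Camera calls ended without S-Exo 2 for amino acid response, heat shock and G2/M (adjusted p = 0.211, 0.0553 and 0.177), without S-Exo 3 for megakaryocyte (0.084), and without NC 2 for cholesterol and mitochondrially encoded genes (0.0697 and 0.507). The library named for each list is the one whose loss raised its adjusted p most, and other losses ended calls too. Of the 10 lists, 4 stayed without S-Exo 2, 7 without S-Exo 3 and 6 without NC 2. Without S-Exo 2, S-Exo 3 and R-Exo 3 the S-Exo group is S-Exo 1 alone, so calls in that setting decide nothing and are not given.

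R-Exo differed from NC across much of the transcriptome. Of 16941 genes tested, 4419 changed, 2276 higher and 2143 lower, and 2329 of them by at least 2-fold. Among genes with a symbol, 1866 rose and 1611 fell. Here and below, rose and fell describe levels in the R-Exo libraries and not a response to the exosomes. The labels do not say whether these cells were of the same stock as NC, so treatment and stock cannot be told apart. Medians of 50 neighbouring genes ran from -0.64 to 0.70 on the log2 scale, as weighed below. Counts of list members are to be read beside the share of all genes that changed.

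**Figure D2:**
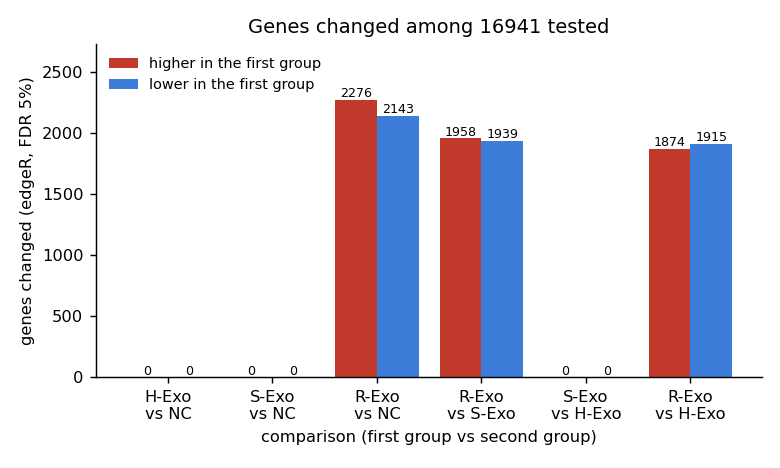
Number of genes (y axis) higher (red) or lower (blue) in the first group of each pair (x axis) by edgeR's quasi-likelihood test at an FDR of 5%, among 16941 genes tested. The 3 pairs with R-Exo have 1874 to 2276 genes in each direction and the other 3 pairs have 0.

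At the upper end stood ABCB1 (chromosome 7, 87503633 to 87713323), which encodes the drug efflux pump P-glycoprotein (3853 ± 875 against 0.853 ± 0.377 CPM, log2 fold change 12.13 ± 1.73, edgeR adjusted p = 3.55e-04). CROT, a peroxisomal acyltransferase gene (chromosome 7, 87345681 to 87399795), stood at 217 ± 41.9 against 0.0215 ± 0.0372 CPM (edgeR adjusted p = 7.61e-04). With 2 counts over the NC libraries, its ratio from summed counts had an exact Poisson 95% interval of 2858 to 85260. MS4A4A, a membrane protein gene known from macrophages (chromosome 11, 60185702 to 60317944), had 39.9 ± 9.36 against 0 CPM, at least 376-fold higher (edgeR adjusted p = 1.59e-04). Other genes at 0 counts in every NC library were UGT8, which makes the glycolipid galactosylceramide (at least 109-fold), GSPT2, a translation termination factor (at least 94.8-fold), and MUM1L1 (at least 80.5-fold). HRASLS, of a phospholipase family (at least 52.2-fold), and ERVMER34-1, an endogenous retroviral envelope gene (at least 51.7-fold), were also at 0. These 8 genes were ranked by fitted fold changes, which for genes at 0 depend on the prior count, so the bounds do not show their order. GSPT2 resembles GSPT1, so its counts are uncertain.

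Among the largest falls of genes with at least 5 CPM in NC was FOXA2, a transcription factor of endoderm-derived tissues (0.112 ± 0.136 against 5.75 ± 0.405 CPM, log2 fold change -5.61 ± 0.64, edgeR adjusted p = 8.11e-05). AL121722.1, which overlaps part of FOXA2 on chromosome 20, where reads cannot be assigned without strand, fell by 81-fold. The kinase gene SYK (chromosome 9, 90801787 to 90898549) fell (0.38 ± 0.723 against 16.4 ± 0.533 CPM, log2 fold change -5.39 ± 0.92, edgeR adjusted p = 0.00113). PRKCH, a protein kinase C, was 36.9-fold lower, NLRP2, an inflammasome-related gene, 32-fold, and ASS1, the argininosuccinate synthase of the urea cycle, 31.1-fold. ACTA2, smooth muscle actin, was 35.7-fold lower. The cancer-testis gene SSX2B was 36.7-fold lower and has a near-identical copy, SSX2, so its count is uncertain. R-Exo 3 held more SYK, PRKCH, NLRP2, ASS1, ACTA2 and SSX2B than the other 3 R-Exo libraries, so these folds rest largely on it. PRKCH and NLRP2 had 0 counts in the other 3.

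**Figure D3:**
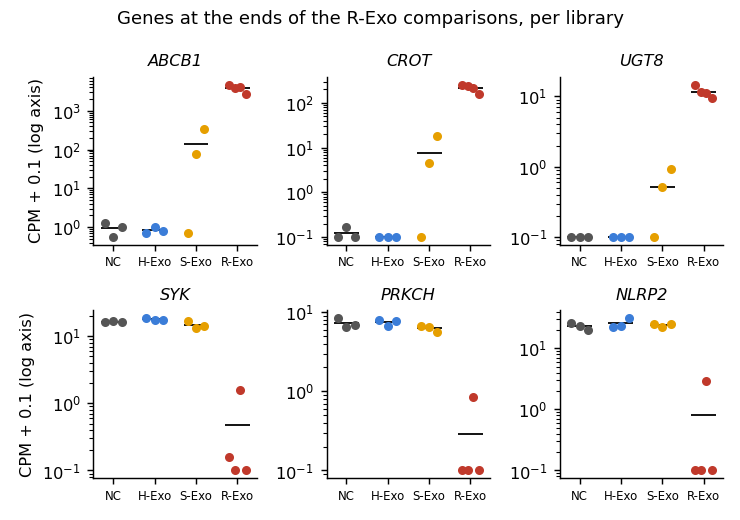
Level of 6 genes in each library (points) and group mean (lines), in CPM on a log axis after adding 0.1, so that a level of 0 lies at 0.1. ABCB1, CROT and UGT8 are highest in R-Exo with S-Exo 2 and S-Exo 3 above S-Exo 1, and SYK, PRKCH and NLRP2 are lowest in R-Exo with R-Exo 3 above the other 3.

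Of 42 erythroid genes 14 rose, 4 fell and 24 did not pass. 19 passed when adjusted over the list alone (camera adjusted p = 0.028, and adjusted p = 0.798 with an estimated correlation). Carbonic anhydrase CA2 rose (38.9 ± 5.84 against 1.31 ± 0.134 CPM, log2 fold change 4.88 ± 0.52, edgeR adjusted p = 5.46e-05), as did the transcription regulators TAL1 (0.97 ± 0.12 on the log2 scale) and LMO2 (1.37 ± 0.18). Glycophorin GYPE rose by 1.16 ± 0.13, and its reads may be shared with other glycophorins. Of 21 megakaryocyte and platelet genes 7 rose, 2 fell and 12 did not pass. 9 passed when adjusted over the list alone (camera adjusted p = 0.0575). GP6, the collagen receptor of platelets, rose (63 ± 14.3 against 3.89 ± 1.08 CPM, log2 fold change 4.02 ± 0.29, edgeR adjusted p = 5.61e-06), and ITGA2B, the integrin alpha chain of the fibrinogen receptor, rose (102 ± 14.5 against 22.1 ± 2.48 CPM, log2 fold change 2.20 ± 0.18, edgeR adjusted p = 1.17e-05). TUBB1 rose by 2.82 ± 0.28, while the tetraspanin CD9 fell (1.82 ± 0.515 against 9.7 ± 1.76 CPM, log2 fold change -2.41 ± 0.27, edgeR adjusted p = 7.87e-05). Of 12 neutrophil and monocyte markers 1 rose, 2 fell and 9 did not pass. 3 passed when adjusted over the list alone (camera adjusted p = 0.981).

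**Figure D4:**
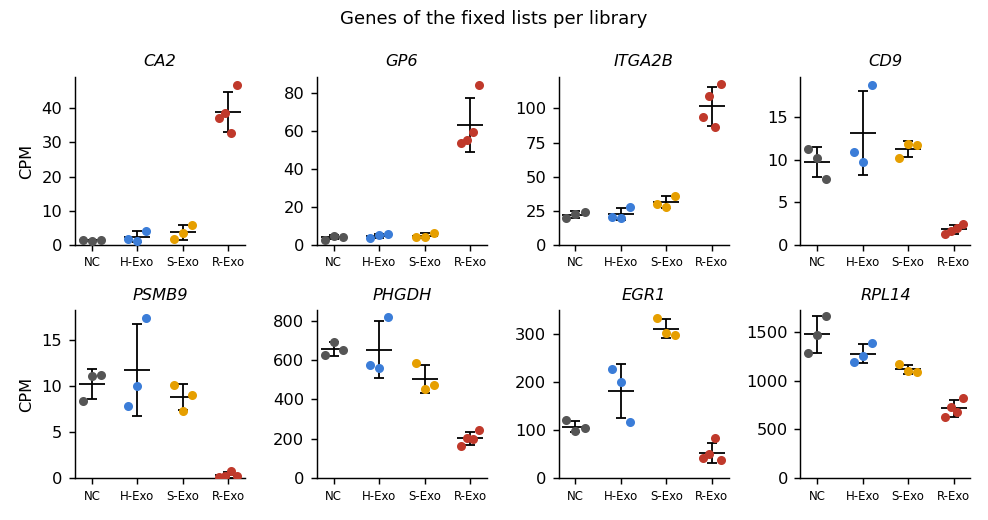
Level (y axis, CPM) of 8 genes from the fixed lists in each library (points), with the group mean and SD (black), for the 4 groups on the x axis. CA2, GP6 and ITGA2B are higher in each R-Exo library than in any other, CD9, PSMB9, PHGDH, EGR1 and RPL14 are lower, and EGR1 is highest in S-Exo.

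Interferon and MHC class I genes were lower as lists. Of 27 interferon response genes 2 rose, 9 fell and 16 did not pass. 13 passed when adjusted over the list alone (camera adjusted p = 0.0114, and adjusted p = 0.388 with an estimated correlation). The viral RNA sensor IFIH1 fell by 14.5-fold, the ISG15 protease gene USP18 by 7.2-fold and the nucleotide kinase CMPK2 by 4.15-fold. Of 10 MHC class I and antigen processing genes 0 rose, 4 fell and 6 did not pass. 5 passed when adjusted over the list alone (camera adjusted p = 0.028, and adjusted p = 0.388 with an estimated correlation). PSMB9, an immunoproteasome subunit, fell (0.345 ± 0.31 against 10.2 ± 1.63 CPM, log2 fold change -4.86 ± 0.49, edgeR adjusted p = 4.04e-05), and the peptide transporter TAP1 fell by 2.46-fold. Inflammatory cytokine and NF-kB targets split, and of 26 genes 6 rose, 7 fell and 13 did not pass. 14 passed when adjusted over the list alone (camera adjusted p = 0.981, with a median of 0.28 and a mean of -0.07). The dendritic cell marker CD83 and the cytokine IL6 fell (-2.31 ± 0.29 and -0.96 ± 0.18 on the log2 scale), while IL23A and the superoxide dismutase SOD2 rose (1.71 ± 0.27 and 0.70 ± 0.12).

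The list on BCR-ABL, kinase inhibitor response and drug transport held 25 tested genes, of which 7 rose, 5 fell and 13 did not pass. 14 passed when adjusted over the list alone (camera adjusted p = 0.3, with a median of 0.30 and a mean of -0.09). Besides ABCB1, the efflux pump ABCC1 rose by 0.78 ± 0.10 on the log2 scale, the carnitine and organic cation transporter SLC22A4 by 1.91 ± 0.25 and protein kinase C alpha, PRKCA, by 1.32 ± 0.13. The receptor kinase KIT fell (1.71 ± 0.941 against 10.6 ± 2.53 CPM, log2 fold change -2.63 ± 0.35, edgeR adjusted p = 2.12e-04). Of 18 genes downstream of STAT5 and BCR-ABL 3 rose, 2 fell and 13 did not pass. Adjusted over the list alone, 6 passed (camera adjusted p = 0.817). STAT5A rose (393 ± 91.2 against 135 ± 8.58 CPM, log2 fold change 1.54 ± 0.17, edgeR adjusted p = 5.46e-05), and BCL6, a repressor that STAT5 opposes, fell (18.7 ± 6.89 against 65.9 ± 9.39 CPM, log2 fold change -1.82 ± 0.31, edgeR adjusted p = 0.00111). Of 30 immediate early and MAPK feedback genes 5 rose, 6 fell and 19 did not pass. 11 passed when adjusted over the list alone (camera adjusted p = 0.981, with a median of 0.12 and a test pointing down). Falls included PHLDA1 (-2.31 ± 0.19 on the log2 scale), the ETS factor ETV5 (-0.99 ± 0.13) and JUNB (-0.84 ± 0.17).

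Of 46 ribosomal protein genes 0 rose, 16 fell and 30 did not pass. 16 passed when adjusted over the list alone (camera adjusted p = 3.75e-06, and adjusted p = 0.798 with an estimated correlation). RPL14 fell (716 ± 85.5 against 1473 ± 190.3 CPM, log2 fold change -1.04 ± 0.13, edgeR adjusted p = 1.36e-04), and RPL32 fell by 2.22-fold. MYC targets and ribosome biogenesis genes were higher, and of 30 genes 9 rose, 0 fell and 21 did not pass. 9 passed when adjusted over the list alone (camera adjusted p = 0.014, and adjusted p = 0.299 with an estimated correlation). POLR1A, the large subunit of RNA polymerase I, rose by 0.79 ± 0.11 on the log2 scale and WDR12, a ribosome assembly factor, by 0.44 ± 0.09. Of 29 G2/M and mitosis genes 0 rose, 2 fell and 27 did not pass. 2 passed when adjusted over the list alone (camera adjusted p = 0.036, and adjusted p = 0.388 with an estimated correlation), the falls being the cell cycle kinase CDK1 (203 ± 40.6 against 391 ± 42.9 CPM, log2 fold change -0.95 ± 0.16, edgeR adjusted p = 0.00122) and the spindle protein NUSAP1 (-0.94 ± 0.17 on the log2 scale). Of 30 G1/S and DNA replication genes 8 rose, 3 fell and 19 did not pass. 11 passed when adjusted over the list alone (camera adjusted p = 0.281). DNA ligase LIG1 and the clamp loader subunit RFC4 fell (-0.68 ± 0.09 and -0.89 ± 0.09), while MCM7 and UNG rose (0.80 ± 0.18 and 1.16 ± 0.27).

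No lipid list passed as a list, while single members changed. Over all genes tested, 4419 of 16941 changed. The share of members that changed lay below this in the cholesterol synthesis and fatty acid oxidation lists, and above it in the fatty acid synthesis and LXR lists. Of 18 fatty acid synthesis and desaturation genes 8 rose, 1 fell and 9 did not pass. 9 passed when adjusted over the list alone (camera adjusted p = 0.0575). Fatty acid synthase FASN rose (537 ± 50.6 against 242 ± 12.9 CPM, log2 fold change 1.15 ± 0.18, edgeR adjusted p = 5.77e-04), as did the desaturase FADS1 (by 1.56 ± 0.15 on the log2 scale), while ACSL1, which activates fatty acids, fell (-1.43 ± 0.14). Of 12 LXR targets and cholesterol efflux genes 1 rose, 5 fell and 6 did not pass. 6 passed when adjusted over the list alone (camera adjusted p = 0.0628). The cholesterol exporter ABCA1 was at 0 counts in R-Exo, at least 11.5-fold lower, and APOE, the lipid carrier, fell by 10.6-fold. Of 28 cholesterol synthesis and uptake genes 5 rose, 1 fell and 22 did not pass. 6 passed when adjusted over the list alone (camera adjusted p = 0.108), with CYP51A1 up (227 ± 27 against 51.6 ± 7.05 CPM, log2 fold change 2.14 ± 0.17, edgeR adjusted p = 1.00e-05), a gene of the run on chromosome 7 described with ABCB1, and MSMO1, the enzyme of a later step, down (-0.84 ± 0.18 on the log2 scale). Of 19 fatty acid oxidation and PPAR target genes 1 rose, 3 fell and 15 did not pass. 4 passed when adjusted over the list alone (camera adjusted p = 0.817, with a median of 0.03 and a mean of -0.03), and the kinase PDK4 rose by 1.66 ± 0.31.

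Stress lists did not pass as lists. Of 28 hypoxia response genes 2 rose, 7 fell and 19 did not pass. 15 passed when adjusted over the list alone (camera adjusted p = 0.0575), with falls of the oxygen sensor EGLN3 (-0.91 ± 0.16 on the log2 scale) and ANGPTL4, a lipase inhibitor (-2.18 ± 0.30). Of 21 endoplasmic reticulum chaperone genes 2 rose, 6 fell and 13 did not pass. 10 passed when adjusted over the list alone (camera adjusted p = 0.0857), with a fall of calreticulin, CALR (-1.04 ± 0.18). Of 29 amino acid response genes 4 rose, 4 fell and 21 did not pass. 8 passed when adjusted over the list alone (camera adjusted p = 0.483). PHGDH, which opens the serine pathway, fell (201 ± 33.1 against 656 ± 34 CPM, log2 fold change -1.70 ± 0.17, edgeR adjusted p = 3.78e-05), and DDIT3 fell, while the cytokine GDF15 rose (1.33 ± 0.23). The oxidative stress list had 23 tested genes, of which 0 rose, 6 fell and 17 did not pass. Adjusted over the list alone, 6 passed (camera adjusted p = 0.281), the falls led by AKR1C1 (-1.60 ± 0.15). The p53 target list had 21, of which 4 rose, 2 fell and 15 did not pass. Adjusted over the list alone, 6 passed (camera adjusted p = 0.384), with the exonuclease AEN up by 1.45 ± 0.13.

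Among the lists that did not pass were those on adhesion and extracellular matrix, exosome release and cell survival. Of 25 adhesion, matrix and migration genes 2 rose, 3 fell and 20 did not pass. Adjusted over the list alone, 5 passed (camera adjusted p = 0.704), with the hyaluronan receptor CD44 up (1.56 ± 0.24 on the log2 scale) and the collagen COL6A1 down (-1.63 ± 0.32). Of 23 exosome biogenesis and release genes 3 rose, 3 fell and 17 did not pass. Adjusted over the list alone, 6 passed (camera adjusted p = 0.981), with RAB27B, a small GTPase of vesicle secretion, up by 2.15 ± 0.41. Of 20 BCL2 family and apoptosis genes 2 rose, 3 fell and 15 did not pass. 5 passed when adjusted over the list alone (camera adjusted p = 0.981, with a median of 0.00 and a mean of -0.07), with the survival gene BCL2 up (2.83 ± 0.465 against 0.922 ± 0.263 CPM, log2 fold change 1.62 ± 0.31, edgeR adjusted p = 0.00239). Of 17 TGF-beta and BMP targets 4 rose, 3 fell and 10 did not pass. 9 passed when adjusted over the list alone (camera adjusted p = 0.981, with a median of -0.06 and a mean of 0.04), SKI rising by 0.81 ± 0.14. Of 36 nuclear oxidative phosphorylation genes 0 rose, 3 fell and 33 did not pass. 3 passed when adjusted over the list alone (camera adjusted p = 0.101). Of 30 autophagy and lysosome genes 4 rose, 3 fell and 23 did not pass. 10 passed when adjusted over the list alone (camera adjusted p = 0.46), with the lysosomal glycoprotein GPNMB down (-2.37 ± 0.39). Of 9 lymphocyte markers 3 rose, 0 fell and 6 did not pass. 4 passed when adjusted over the list alone (camera adjusted p = 0.258), CD22 and CD3D rising by 1.67 ± 0.24 and 2.36 ± 0.40.

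KEGG pathways were tested over the 6730 tested genes that carry an annotation, 317 pathways in each direction, with a one-sided Fisher's exact test. Higher genes were enriched in spinocerebellar ataxia, with 38 of 148 genes against 20.5 by chance (adjusted p = 0.0263, 1.85-fold). Among them were PRKCA and the stress sensor kinase ERN1. Lower genes were enriched in maturity onset diabetes of the young, with 8 of 13 against 1.71 by chance (adjusted p = 0.0190, 4.69-fold). They included FOXA2, the overlapping AL121722.1 and the Notch target HES1. Reads of FOXA2 and AL121722.1 cannot be told apart, so the same signal may be counted for both. The pathway was not tested with them joined, so its call is uncertain. Among genes changed at least 2-fold, 9 pathways passed.

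Leaving out H-Exo 3 and R-Exo 4 raised the count of genes changed to 8287, and leaving out S-Exo 2, S-Exo 3 and R-Exo 3 lowered it to 2808. Without NC 1 the camera calls for erythroid, interferon, MHC class I and G2/M genes ended (adjusted p = 0.0609, 0.0567, 0.111 and 0.0812). Without S-Exo 2, S-Exo 3 and R-Exo 3 those for MHC class I and G2/M ended (0.168 and 0.0853).

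ABCB1 and CROT lie in a run of higher genes on chromosome 7, a region chosen after its values were seen. Between 86 and 93 Mb, 30 genes were tested, of which 25 rose, 0 fell and 5 did not pass, and 19 of those that rose were at least 4-fold higher. The mitochondrial carrier SLC25A40 rose from 31.2 ± 3.24 CPM in NC to 919.6 ± 80.6 CPM in R-Exo, KIAA1324L from 77.0 ± 14.4 to 1695 ± 306 CPM and the cell cycle kinase CDK6 from 45.3 ± 6.36 to 259.8 ± 80.6 CPM. Their edgeR adjusted p-values were 5.61e-06, 1.89e-05 and 0.000166.

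**Figure D5:**
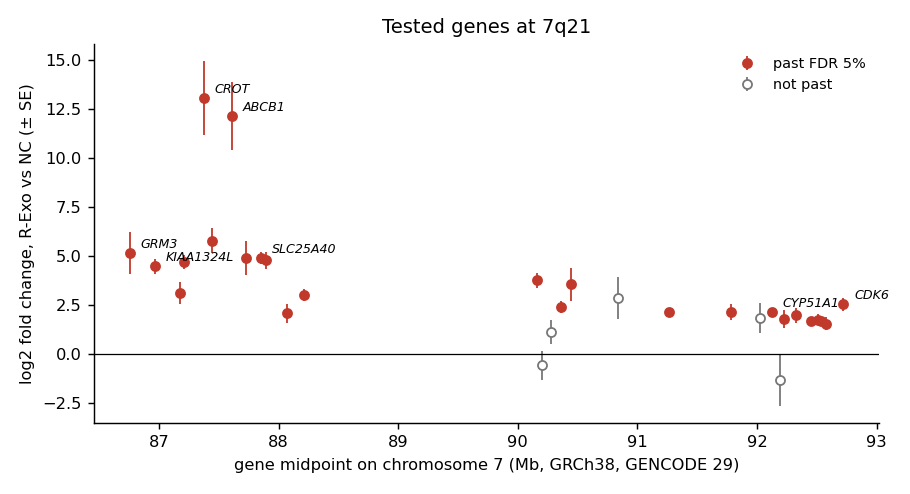
Log2 fold change of R-Exo against NC with its SE (y axis) for the 30 tested genes between 86 and 93 Mb of chromosome 7 (x axis, gene midpoint on GRCh38), filled where past an FDR of 5%. The 25 filled points all lie above 0, with CROT and ABCB1 highest.

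R-Exo and S-Exo, compared directly, differed in 3897 genes, 1958 higher and 1939 lower in R-Exo, 2074 of them by at least 2-fold. Among genes with at least 5 CPM in the higher group, the largest rises included C3orf52 (50.4-fold), the cancer-testis gene SSX1 (99 ± 33.1 against 2.42 ± 2.38 CPM, log2 fold change 5.36 ± 0.66, edgeR adjusted p = 1.77e-04), ERVMER34-1 (40.7-fold) and the forkhead gene FOXN3 (37.8-fold). Others were the kinase MAP3K9 (36.8-fold), the phosphatase subunit PPP2R2B (36.8-fold) and guanine deaminase GDA (31.6-fold). Falls included EREG, an EGF receptor ligand (1.78 ± 3.49 against 66.1 ± 11 CPM, log2 fold change -5.20 ± 1.21, edgeR adjusted p = 0.00862), CBR1, a carbonyl reductase (29.9-fold), ZNF738 (27.5-fold), SYK (37.8-fold), PRKCH (31.7-fold), NLRP2 (33.5-fold) and SSX2B (37.5-fold). INO80B-WBP1, a readthrough locus that shares exons with its neighbours and is uncertain for that reason, had 0 counts in R-Exo, at least 126-fold lower. SSX1 and SSX2B belong to a family of close copies and are uncertain too. These folds rest on few libraries. In S-Exo 1, C3orf52, ERVMER34-1, FOXN3, MAP3K9 and PPP2R2B had 0 counts, so their S-Exo levels come from S-Exo 2 and S-Exo 3 (for ERVMER34-1 from S-Exo 3 alone). ZNF738, PRKCH and NLRP2 had 0 counts in each R-Exo library but R-Exo 3, and EREG, CBR1, SYK and SSX2B were highest there, so without it several of these folds would be bounds.

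Immediate early genes differed between these groups, and of 30 genes 2 rose, 13 fell and 15 did not pass. 18 passed when adjusted over the list alone (camera adjusted p = 0.027, and adjusted p = 0.492 with an estimated correlation). EGR1 was lower in R-Exo (53.1 ± 20.8 against 311 ± 19.8 CPM, log2 fold change -2.55 ± 0.27, edgeR adjusted p = 8.11e-05), as were JUNB (-1.50 ± 0.17 on the log2 scale) and PHLDA1 (-2.23 ± 0.19). Of 29 G2/M and mitosis genes 0 rose, 8 fell and 21 did not pass. 8 passed when adjusted over the list alone (camera adjusted p = 0.00161, and adjusted p = 0.161 with an estimated correlation), including CDK1 (203 ± 40.6 against 437 ± 29.3 CPM, log2 fold change -1.11 ± 0.16, edgeR adjusted p = 5.42e-04) and KIF20A, a kinesin of late mitosis (-0.75 ± 0.15). Of 28 hypoxia response genes 2 rose, 12 fell and 14 did not pass. 16 passed when adjusted over the list alone (camera adjusted p = 0.00574, and adjusted p = 0.291 with an estimated correlation), with the mitophagy receptor BNIP3L lower by 1.8-fold. Interferon response genes were lower, and of 27 genes 0 rose, 9 fell and 18 did not pass. 11 passed when adjusted over the list alone (camera adjusted p = 0.00574, and adjusted p = 0.291 with an estimated correlation). Of 10 MHC class I genes 0 rose, 4 fell and 6 did not pass. 4 passed when adjusted over the list alone (camera adjusted p = 0.027, and adjusted p = 0.365 with an estimated correlation), with PSMB9 25.1-fold lower.

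Endoplasmic reticulum chaperones were lower as well, and of 21 genes 1 rose, 8 fell and 12 did not pass. 9 passed when adjusted over the list alone (camera adjusted p = 0.0492, and adjusted p = 0.59 with an estimated correlation), with the chaperone HSPA5 at 1121 ± 41 against 1999.9 ± 351 CPM. Of 12 LXR targets 1 rose, 4 fell and 7 did not pass. 5 passed when adjusted over the list alone (camera adjusted p = 0.0297, and adjusted p = 0.365 with an estimated correlation), with the scavenger receptor CD36 6.1-fold lower. Of 19 replication-dependent histones, whose near-identical copies make single genes uncertain and whose transcripts largely lack poly-A tails, 1 rose, 5 fell and 13 did not pass. 8 passed when adjusted over the list alone (camera adjusted p = 0.0492, and adjusted p = 0.591 with an estimated correlation). MYC targets and ribosome biogenesis genes were the only list past upward, and of 30 genes 10 rose, 0 fell and 20 did not pass. 10 passed when adjusted over the list alone (camera adjusted p = 0.027, and adjusted p = 0.291 with an estimated correlation), with CAD, of pyrimidine synthesis, up by 0.52 ± 0.11 on the log2 scale. No KEGG pathway passed Fisher's exact test in either direction, and 1 did among genes changed at least 2-fold. Without S-Exo 2 the count was 2430 genes, and without H-Exo 3 and R-Exo 4 it was 6909. The camera calls for LXR targets, endoplasmic reticulum chaperones and histones ended without R-Exo 3 (adjusted p = 0.0719, 0.115 and 0.115), and that for MHC class I without S-Exo 1 (0.16). For each list only the loss that raised its adjusted p most is named, and other losses ended calls too. Of the 9 lists, 5 stayed without R-Exo 3, 6 without S-Exo 2 and 6 without S-Exo 3. With S-Exo 2, S-Exo 3 and R-Exo 3 left out S-Exo 1 stands alone for its group, so no conclusion is drawn from that setting.

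S-Exo against H-Exo gave no gene past the threshold. ABCB1 had one of the lowest p-values (141 ± 181 against 0.738 ± 0.166 CPM), with S-Exo 1 near the H-Exo level and S-Exo 2 and S-Exo 3 above it. FOS stood at 29.7 ± 0.583 against 10.9 ± 3.12 CPM, TUBB1 at 5.38 ± 0.414 against 2.22 ± 0.896 CPM, and TMEM163, a zinc-binding membrane protein, at 0.239 ± 0.135 against 0 CPM, all at an edgeR adjusted p of 0.836. Genes of 5 lists were lower in S-Exo and 0 lists were higher, a direction that turned on H-Exo 3, since without it 11 lists were higher and 2 lower. The 5 had 0 members past when adjusted over the list alone. Ribosomal protein genes had a median of -0.38 over 46 (camera adjusted p = 1.06e-11, and adjusted p = 0.767 with an estimated correlation), with RPL11 at 1091 ± 11.2 against 1358 ± 130.4 CPM. Mitochondrially encoded genes had -0.34 over 13 (camera adjusted p = 4.81e-04, and adjusted p = 0.767 with an estimated correlation), with MT-ND3 at 429.6 ± 50.2 against 742 ± 38 CPM. Nuclear genes of oxidative phosphorylation had -0.31 over 36 (camera adjusted p = 0.00196, and adjusted p = 0.767 with an estimated correlation), with NDUFA1 at 45.5 ± 8.22 against 67.3 ± 10.4 CPM. Amino acid response genes had -0.21 over 29 (camera adjusted p = 0.00138, and adjusted p = 0.767 with an estimated correlation), with the serine phosphatase PSPH at 47.3 ± 4.31 against 63.6 ± 9.58 CPM. Oxidative stress genes had -0.24 over 23 (camera adjusted p = 0.0466, and adjusted p = 0.767 with an estimated correlation), with the quinone reductase NQO1 at 35.2 ± 3.13 against 51.4 ± 11.8 CPM.

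In edgeR 0 of 16941 genes passed, with 778 at an unadjusted p under 0.05 against 847 by chance, while DESeq2 called 28, limma on FPKM 0, and edgeR without H-Exo 3 and R-Exo 4 called 191. Without H-Exo 3 the calls for oxidative phosphorylation, amino acid response and oxidative stress ended (camera adjusted p = 0.159, 0.151 and 0.87), and oxidative phosphorylation then pointed up. The setting without S-Exo 2, S-Exo 3 and R-Exo 3 leaves S-Exo 1 alone against H-Exo, so its calls are not given.

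R-Exo against H-Exo gave 3789 genes, 1874 higher and 1915 lower, 2087 of them by at least 2-fold. CROT had 0 counts in H-Exo (at least 2041-fold higher in R-Exo) and ABCB1 stood at 3853 ± 875 against 0.738 ± 0.166 CPM (edgeR adjusted p = 3.87e-04). Also at 0 in H-Exo were FOXN3 (at least 156-fold), the amyloid precursor adaptor APBB2 (at least 134-fold), TESPA1, of T-cell receptor signalling (at least 111-fold), and F2RL2, a thrombin receptor (at least 91.3-fold). UGT8 and GSPT2 were at 0 in both H-Exo and NC. Among genes with at least 5 CPM in H-Exo the falls were led by AL121722.1 (77.8-fold), SYK (45.3-fold), FOXA2 (45-fold), SSX2B (44.1-fold) and ACTA2 (42.4-fold). SYK, SSX2B and ACTA2 were highest in R-Exo 3 among the R-Exo libraries, so the size of their folds rests largely on it.

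Interferon genes were lower in R-Exo, and of 27 genes 0 rose, 10 fell and 17 did not pass. 13 passed when adjusted over the list alone (camera adjusted p = 6.37e-04, and adjusted p = 0.3 with an estimated correlation), with USP18 at 0.67 ± 0.138 against 6.83 ± 3.65 CPM. Of 10 MHC class I genes 0 rose, 4 fell and 6 did not pass. 4 passed when adjusted over the list alone (camera adjusted p = 0.0064, and adjusted p = 0.3 with an estimated correlation). Of 46 ribosomal protein genes 0 rose, 10 fell and 36 did not pass. 14 passed when adjusted over the list alone (camera adjusted p = 2.90e-06, and adjusted p = 0.788 with an estimated correlation), with RPL13 at 1112 ± 347 against 2494 ± 964 CPM. Of 36 nuclear oxidative phosphorylation genes 0 rose, 4 fell and 32 did not pass. 3 passed when adjusted over the list alone (camera adjusted p = 0.00937, and adjusted p = 0.938 with an estimated correlation), with the succinate dehydrogenase subunit SDHD 2.07-fold lower. Of 29 G2/M genes 0 rose, 6 fell and 23 did not pass. 6 passed when adjusted over the list alone (camera adjusted p = 0.0215, and adjusted p = 0.3 with an estimated correlation). Of 28 hypoxia genes 0 rose, 11 fell and 17 did not pass. 14 passed when adjusted over the list alone (camera adjusted p = 0.0215, and adjusted p = 0.33 with an estimated correlation). Of 12 LXR targets 0 rose, 5 fell and 7 did not pass. 5 passed when adjusted over the list alone (camera adjusted p = 0.022, and adjusted p = 0.33 with an estimated correlation), and APOE was 12.2-fold lower. MYC targets were higher, and of 30 genes 3 rose, 0 fell and 27 did not pass. 2 passed when adjusted over the list alone (camera adjusted p = 0.045, and adjusted p = 0.3 with an estimated correlation). Lower genes were enriched in the same diabetes pathway, with 8 of 13 genes against 1.62 by chance (adjusted p = 0.0127 by Fisher's exact test), and 13 pathways passed among genes changed at least 2-fold. The 8 again include FOXA2 and the overlapping AL121722.1, so the diabetes call is uncertain here too.

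The edgeR count for R-Exo against H-Exo was 2071 on the 2 groups alone, 6159 without H-Exo 3 and R-Exo 4, and 2367 without S-Exo 2, S-Exo 3 and R-Exo 3. Camera calls ended without H-Exo 3 for oxidative phosphorylation, LXR targets, MHC class I and hypoxia (adjusted p = 0.647, 0.167, 0.1 and 0.0532), without R-Exo 4 for G2/M (0.0727) and without H-Exo 1 for MYC targets (0.114). Each list is given with the loss that raised its adjusted p most, and 6 of the 8 calls stayed without R-Exo 4. Without H-Exo 3 the lists past were 5 higher and 3 lower, against 1 higher and 7 lower with it. Without S-Exo 2, S-Exo 3 and R-Exo 3 only 2 of the 8 calls, for interferon and ribosomal protein genes, stayed.

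Over the 3 R-Exo comparisons 2737 genes changed in the same direction in each, 1341 higher and 1396 lower, of 5557 changed in any. The comparisons share the same R-Exo libraries, so part of this agreement is built in. Between the treatments against NC, 0 genes were called in both members of any pair, since H-Exo and S-Exo had no calls in edgeR. The fold changes against NC correlated across 11345 genes, which are not independent replicates, at r = 0.289 for H-Exo with S-Exo, 0.316 for H-Exo with R-Exo and 0.373 for S-Exo with R-Exo. Unchanged groups simulated against the same NC libraries, 20 times, gave mean r of 0.499, 0.534 and 0.533. The covariance exceeded the simulated mean by 0.0332 for S-Exo with R-Exo and by 0.0123 for H-Exo with R-Exo, and for H-Exo with S-Exo the difference was -0.0244. In that last pair the covariance was 0.0213 against a simulated mean of 0.0457, so the simulated spread may not match that of the libraries. The 3 differences therefore decide nothing about a shared response. Cells, RNA or reads of the R-Exo kind in S-Exo 2 and S-Exo 3, weighed below, could also add to the covariance of S-Exo with R-Exo. With 3 NC libraries the controls could not be split into parts of at least 2, so part of the covariance may come from the shared controls.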

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

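The tests on the 7q21 region, the shares of mixed libraries and the shared batch were chosen after the results were seen, while the GC test and the splits of the samples were chosen before. Dixon's test for a sample far from the others of its group applies to R-Exo, the one group with at least 4 libraries. The gap between the extreme library and its nearest neighbour, over the whole range, was past the 95% limit for 21 of 136 values tested (the genes named in the text, library totals and others), where chance gives about 1 in 20.

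R-Exo 3 was the highest for NLRP2, PRKCH and ZNF738 (each 1), EREG (0.984), SSX2B (0.965), SYK (0.961), SSX2 (0.949), CBR1 (0.948), PHLDA1 (0.900), ASS1 (0.891) and ACTA2 (0.849). SSX2 and SSX2B share reads, so they are not separate values. R-Exo 4 was the highest for CD3D (0.957), TMEM163 (0.948), NQO1 (0.871), STAT5A (0.858), MS4A4A (0.853) and the total count (0.848). R-Exo 2 was highest for RPS24 (0.867) and lowest for PRKCA (0.871), and R-Exo 1 was highest for SKIL (0.851) and lowest for DDIT3 (0.864).

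In R-Exo against NC, 1 of 35 splits of the 7 libraries gave as many genes, the real one (4419 genes, highest other split 1218). That is the lowest share 35 splits can give, so chance is argued against for the gene count but not excluded. The splits show that the libraries group by label. They do not tell treatment from stock, and the libraries of a group may be technical replicates. R-Exo against S-Exo also had 1 of 35 (3897 against at most 841). For R-Exo against H-Exo it was 1 of 35 too, but another split reached 3311 beside the real 3789. That split set R-Exo 1, R-Exo 3, H-Exo 1 and H-Exo 2 against R-Exo 2, R-Exo 4 and H-Exo 3, so it follows H-Exo 3 and R-Exo 4 and points to a structure of the samples. For gene lists, chance is not excluded: 14 of 35 splits had as many for R-Exo against NC (6 lists, highest other 9), 7 of 35 for R-Exo against S-Exo (9, highest other 12) and 25 of 35 for R-Exo against H-Exo (8, highest other 16). For pathways the counts were 1 of 35 against NC (2, highest other 1), 35 of 35 against S-Exo (0, highest other 1) and 4 of 35 against H-Exo (1, highest other 17). A split with 0 genes changed can have no pathway, and most of the other splits against NC had 0, so the pathway count there restates the gene count and says nothing more about chance. The 35 of 35 against S-Exo follows from the real count of 0 and decides nothing.

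With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In H-Exo against NC 10 of 10 splits had as many genes (real 0, highest other 0) and 10 of 10 as many lists (3, highest other 15). In S-Exo against NC the values were 10 of 10 for genes (0, highest other 1) and 1 of 10 for lists (10, highest other 5). In S-Exo against H-Exo they were 10 of 10 for genes (0, highest other 0) and 10 of 10 for lists (5, highest other 16). Beside a real count of 0 every split is as large, so the 10 of 10 for genes was fixed in advance and decides nothing. The 0 counts are edgeR's, with 426, 1244 and 778 genes at an unadjusted p under 0.05 and 7, 120 and 28 by DESeq2, and 0 by limma on FPKM in each.

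The first pattern is the run of higher genes around ABCB1 and CROT, together with genes near 0, in the R-Exo libraries. Transcripts carried in by exosomes are argued against for the falls, since 41 genes of 10726 at 5 CPM or more in each NC library were over 16-fold lower in R-Exo, with 0 such genes in H-Exo and in S-Exo. Added RNA could not lower single genes this far, so the falls say nothing about the rises. For the rises carried transcripts were not tested and stay open. A candidate explanation is that the R-Exo cells differ in copy number, as another stock or subline of K562 would. Medians of 50 neighbouring genes varied 2.86 times as much as in 1000 permutations of gene order in R-Exo, against 1.63 in H-Exo and 2.05 in S-Exo. After removing a GC trend the ratios were 2.84, 1.03 and 1.09. The SD of the 50-gene medians was 0.225 in R-Exo, above the highest value of 0.0886 in the permutations. The SD also passed the highest permutation in H-Exo (0.0523 against 0.0370) and S-Exo (0.0864 against 0.0488). The ratio of 2.84 after the GC trend was removed shows that neighbouring genes shifted together in R-Exo. Permuted gene order treats genes as independent, so it cannot tell copy number from a response that neighbours share. A response therefore stays open for the shared shifts and for single genes among the 4419 changed, since stock and treatment cannot be told apart.

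The second pattern is that S-Exo 2 and S-Exo 3 lie between S-Exo 1 and R-Exo for genes such as ABCB1. A share of cells, RNA or reads of the R-Exo kind may explain it: 7 genes not known to lie on chromosome 7 gave median shares of 2.06% and 7.22% of the R-Exo level, beside 2.01% and 9.23% for ABCB1, and the ratio of the shares farther from 1 was 0.783. They include an unannotated locus without a known position. S-Exo 1 had 0%. In R-Exo 3, 10 genes near 0 in the other R-Exo libraries stood at a median of 12.2% of the level in NC and H-Exo, which a share of cells, RNA or reads of that kind could give. ABCB1 differed 564-fold between the highest and lowest S-Exo library, which goes against a response to S-Exo that all 3 share. A response that differs between them stays open, since the labels do not say whether they had the same exosomes.

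The third pattern is that H-Exo 3 and R-Exo 4 stand apart from their groups, and no biological explanation was tested for it. GC content or transcript length may contribute: deviations from the mean of the other libraries of the group correlated with GC content at rho = 0.633 and 0.578. S-Exo 1 had 0.656 and did not stand apart, but its deviations were smaller (SD 0.296, against 0.918 in H-Exo 3 and 0.753 in R-Exo 4). GC content and length together held 51.5% and 47.9% of the variance of the deviations in these 2 libraries, and 31.5% in S-Exo 1. In R-Exo 1, with an SD of 0.386, they held 48.6%, so this stays open. A library or sequencing batch that the 2 libraries share stays open too. Their deviations correlated at r = 0.871 across genes, but the pair was picked for lying together on the second principal component, so this value decides nothing, and the labels give no batch.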

How the results depend on the processing

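The settings without H-Exo 3 and R-Exo 4, and without S-Exo 2, S-Exo 3 and R-Exo 3, were chosen after seeing the data, and the others before. The setting without S-Exo 2, S-Exo 3 and R-Exo 3 left S-Exo 1 alone in its group, and the tallies that follow include it. Over all settings, 157 counts of genes, lists, pathways or overlaps stayed within 1.5 times their main value and 59 did not. Single calls stayed on their side of the threshold with their direction in 1919 cases for named genes and 270 for lists. Of the rest, 126 and 136 lost the call, 35 gene results gained one, and 2 and 4 reversed. The cause was not tested unless stated. Changing the scaling shifted fold changes by less than 0.01 on the log2 scale and moved no count of genes or lists by over 1.5 times.

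Without H-Exo 3 and R-Exo 4 the genes changed were 1 for H-Exo against NC, 565 for S-Exo against NC, 8287 for R-Exo against NC, 6909 for R-Exo against S-Exo, 191 for S-Exo against H-Exo and 6159 for R-Exo against H-Exo. Of the 8287, 4402 were among the 4419 of the main analysis. Lists past were then 10 for R-Exo against NC and 16 for S-Exo against H-Exo. The latter were 14 higher and 2 lower, and 3 of them were among the 5 of the main analysis, which were lower there. H-Exo against NC had 4 lists, all lower, with 0 of the main 3, all higher. The erythroid list of H-Exo against NC then pointed down (adjusted p = 0.535) and the oxidative phosphorylation list of S-Exo against H-Exo up (0.0365). Without S-Exo 2, S-Exo 3 and R-Exo 3, a setting with fewer samples, the genes were 2808, 898 and 2367 for R-Exo against NC, S-Exo and H-Exo. Lists were 2 for R-Exo against H-Exo. In the pairs with S-Exo, S-Exo 1 stood alone, so the gene count against S-Exo decides nothing and the list counts of those pairs are not given.

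DESeq2 called 7, 120 and 28 genes for H-Exo against NC, S-Exo against NC and S-Exo against H-Exo, where edgeR called 0 (426, 1244 and 778 at an unadjusted p under 0.05) and limma on FPKM 0. On the 2 groups alone edgeR called 203 for S-Exo against NC and 2071 for R-Exo against H-Exo, and R-Exo against NC had 11 lists. By construction, requiring a 2-fold change lowered the R-Exo counts to 2329, 2074 and 2087 against NC, S-Exo and H-Exo, and pathways were then 9, 1 and 13. With no filter beyond 1 count, H-Exo against NC had 7 lists. Camera with an estimated correlation gave 0 lists in each of the 6 pairs. With fry there were 0 for H-Exo against NC, 2 for S-Exo against NC, 13 for R-Exo against NC, 14 for R-Exo against S-Exo, 0 for S-Exo against H-Exo and 13 for R-Exo against H-Exo.

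Leaving out each library in turn gave 0 to 2 genes (highest without NC 1) for H-Exo against NC, 0 to 5 for S-Exo against NC and 0 to 4 for S-Exo against H-Exo (both highest without S-Exo 1). The R-Exo ranges were 3094 (without NC 3) to 4715 against NC, 2430 (without S-Exo 2) to 3825 against S-Exo and 2959 (without R-Exo 1) to 4493 against H-Exo, each highest without R-Exo 4. Lists ranged from 3 (without H-Exo 3) to 10 (without H-Exo 2) for H-Exo against NC and from 5 (without S-Exo 2) to 12 (without S-Exo 1) for S-Exo against NC. For R-Exo they ranged from 2 (without NC 1) to 10 (without R-Exo 4) against NC, from 5 (without R-Exo 3) to 11 (without R-Exo 4) against S-Exo, and from 7 (without H-Exo 1) to 9 (without R-Exo 2) against H-Exo. For S-Exo against H-Exo they ranged from 4 (without S-Exo 2) to 13 (without H-Exo 3). Where a lost list call is tied to a library, that library is the one whose loss raised the adjusted p most. Losing another library may have ended the call too. Without H-Exo 3 the 3 lists of H-Exo against NC were all lower, with 0 shared with the main 3, and the 13 of S-Exo against H-Exo were 11 higher and 2 lower, with 2 shared with the main 5. The 8 of R-Exo against H-Exo were then 5 higher and 3 lower, with 4 shared with the main 8 (1 higher and 7 lower). Genes shared between 2 treatments against NC ranged from 0 to 2 (without NC 1) in each pair of treatments.

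Without H-Exo 3 the erythroid list of H-Exo against NC reversed (adjusted p = 0.513), as did oxidative phosphorylation in S-Exo against H-Exo (0.159). The complement gene C3, not past in the main analysis, reversed in R-Exo against S-Exo without S-Exo 1 (-0.03 on the log2 scale, edgeR adjusted p = 0.972) and in R-Exo against H-Exo without H-Exo 1 (-0.10, edgeR adjusted p = 0.878). The replicate numbers gave no ground for pairing, with 5 of 18 comparisons between groups best for the library of the same number (r from -0.476 to 0.477), and a replicate block gave 4075, 3140 and 3826 genes for R-Exo against NC, S-Exo and H-Exo. With the block, camera calls ended for megakaryocyte genes in S-Exo against NC (adjusted p = 0.067) and G2/M in R-Exo against NC (0.0512). In R-Exo against H-Exo those for G2/M and MYC targets ended (0.0862 for each). Depth limits genes near the floor of 0.106 CPM, where folds are bounds.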

Other observations

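The adjustment of the deposited p-values, the medians by chromosome and the numbers of genes with counts were chosen after the data were seen. Per the deposited DESeq2 columns the authors called 42 genes up and 60 down for H-Exo against NC, 1549 and 1547 for R-Exo against H-Exo, 157 and 119 for S-Exo against H-Exo, and 1888 and 1762 for R-Exo against S-Exo. The columns name each pair in the reverse order, and up was taken to mean higher in the group named second, which was not checked. Those calls use an unadjusted p of 0.05 and a fold of 1.5. With the deposited p-values adjusted by the Benjamini-Hochberg method and no fold minimum, 1, 3079, 27 and 4445 genes lie under 0.05 in the order given. The 2 sets of counts use different thresholds. The median log2 change of R-Exo against NC by chromosome was -0.43 on chromosome 13, -0.24 on chromosome 3, 0.23 on chromosome 14 and 0.19 on chromosome 4. Genes with at least 1 count numbered 20897 in NC 3 and from 17761 (H-Exo 3) to 19381 (R-Exo 3) in the other 12 libraries.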
